A study of Coregonus migratorius and Coregonus peled with 8 samples.

How the data were processed

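The series measured messenger RNA of whole larvae of 2 Siberian whitefishes, the Baikal omul (Coregonus migratorius) and the peled (Coregonus peled), by sequencing of poly(A) RNA on an Illumina NovaSeq instrument, per the labels' protocols. RNA was extracted larva by larva and then combined, so that each library stands for a pool of 12 to 16 larvae. There were 8 libraries in 8 groups, 1 library for each combination of species and state. The 4 states were larvae from nature, an unheated aquaculture control, acute stress (21 °C for 1 h) and chronic stress (21 °C for 24 h, 3 times a week). The aquaculture larvae, heated or not, had been kept for 1.5 months at 9 to 12 °C. They are called aquaculture-reared here, which takes in 6 libraries.

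The deposited value of each gene in each library is a normalized expression signal, not a read count. The values are not whole, never negative and sum to different totals in different libraries, and neither the labels nor the file headers name their unit. Whether they were scaled for gene length, or between libraries, is not given in the sources used here. Trimmomatic 0.36 and edgeR 4.0.3 are named, with no role, per the submitters' processing notes. The assembler, the quantifier and any annotation are not given in the sources used here. The 2184 features carry Trinity identifiers, the form that this de novo transcriptome assembler writes, and are called genes here. The files do not pair these identifiers with gene names and no reference was used, so the 30 gene lists that had been fixed (heat shock proteins, digestive enzymes, muscle and others) could not be matched or tested, and no gene is named beyond its identifier.

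The deposited list of genes is a selection whose rule is not stated. Each gene reached at least 8.20 in some library, and the smallest log2 range of a gene over the 8 libraries was 2.25, so the list holds no gene of steady level. Adjusted p-values therefore refer to the listed genes alone and not to the transcriptome, and shares of genes that differ describe this selection. Sequencing depth is unknown. Low values were compared with multiples of a single step per library, and between 14.9% and 40% of them lay within 0.1 of a whole multiple, where chance gives 20%. Reads were not recovered in this way, so no counting interval is given. A step that differs from gene to gene was not tested. A value of exactly 0 is described as listed at 0.

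The main test had been chosen for counts, as a quasi-likelihood test, and these values are not counts, so the test chosen in advance for normalized values was used. This was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(value + 1), with species and state as additive terms over all 8 libraries. Genes with a mean value of at least 1 were to be tested, a filter that removed 0 genes, and an adjusted p (Benjamini-Hochberg) below 0.05 was called. Differences are on the log2(value + 1) scale, which understates the change of genes with low values. With 1 library per group the additive model has 3 residual degrees of freedom, and its error is the departure of the species from a common difference. It tests the mean difference over both species, and with a common spread a gene that differs mainly in 1 species can pass. The p-values measure the spread over these pooled libraries of different species, not over replicate pools. The prior degrees of freedom estimated by limma were infinite in this fit, so that genes of similar level were given a common spread, whereas they were 5.54 in the fit of the 6 aquaculture-reared libraries, a fit also chosen in advance. Comparisons of species within the aquaculture-reared libraries (species and state additive, 2 residual degrees of freedom) and of the species difference between origins (heat states standing in for replicates, 4 residual degrees of freedom) were added after the data had been seen.

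Within a species, the log2 ratio of 2 single libraries was taken, and genes at least 2-fold apart with a value of at least 10 in the higher library were counted, with no test. The value of 10 was chosen after the data had been seen in place of a planned count minimum. Agreement between species was described by Pearson's and Spearman's correlation of these ratios across genes. Gene sets chosen in the libraries of a species were read in the other species, and their median was placed among 10000 random lists of the same size matched on mean level. Overlaps of comparisons that share a control library were set beside 100 simulations of unchanged groups.

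Genes to be named were picked by a rule fixed before the data were examined, except that its minimum in counts could not be applied as written. For each contrast these are at most 2 higher and 2 lower identifiers with the largest difference among those called with the same sign in each species (for the species contrast, in each state), filled up, as values only, by the largest differences shared by both species. Some filled-up genes lay below a value of 10 in 1 species, such as TRINITY_DN75747_c0_g2, at 4.08 in the omul control. The statistics were tested on simulated data with 200 changed genes among 2184. In the 8-library fit, 0% of simulated log2 changes of 1, 5% of changes of 2, 25.5% of changes of 4 and 70% of changes of 6 were called for the acute contrast, with 2 false calls among 52. In the 6-library fit the shares were 9.09%, 55.4%, 78.3% and 100%, with 5 false calls among 130. For the species contrast over 8 libraries they were 2.08%, 10%, 77.6% and 96.2%, with 3 false calls among 98. The simulated noise was independent between genes and libraries. Each gene was given its own residual SD as its true spread, whereas the 8-library fit of the data gave genes of similar level a common spread. The shares called in that fit may therefore differ from the simulated ones.

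Alternatives were other pseudocounts, the 6 aquaculture-reared libraries alone, each library left out in turn, no state term, other fold and value limits, a common median, a prior without a trend and sums over Trinity components.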

Results

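The data describe how larvae of the Baikal omul and of the peled, both coldwater whitefishes, differed in gene expression after rapid or repeated warming, and how larvae from nature differed from larvae reared in aquaculture. Each of the 8 groups was a single pooled library, so no group has replicates. A difference within a species has no replicate check. A difference between states could be tested only as its mean over both species, with n = 2 libraries per state (1 per species), and a difference between species only over several states. The 2184 listed genes are known by assembly identifier alone and were selected by an unstated rule, so each count below refers to this list. Summed values per library ran from 79169 in acutely stressed peled to 228369 in peled from nature, and median values from 8.70 to 10.9. Between 6 and 74 genes per library were listed at 0, and the 10 highest genes held 19.7% to 36.4% of the summed value. Sequencing depth is unknown.

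Among the listed genes, the libraries fell into 3 clusters. The 3 aquaculture-reared omul libraries correlated with each other at r = 0.91 to 0.93 across genes, and the 3 aquaculture-reared peled libraries at 0.86 to 0.89. Between these species blocks r was 0.10 to 0.25. The libraries from nature formed the remaining cluster, with r = 0.93 between omul and peled. Nature omul correlated with aquaculture-reared omul at 0.65 to 0.68 and with aquaculture-reared peled at 0.36 to 0.51. Nature peled correlated with aquaculture-reared omul at 0.64 to 0.65 and with aquaculture-reared peled, its own species, at 0.22 to 0.41. These correlations run across genes, which are not independent replicates, and across a list from which genes of steady level are missing.

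**Figure D1:**
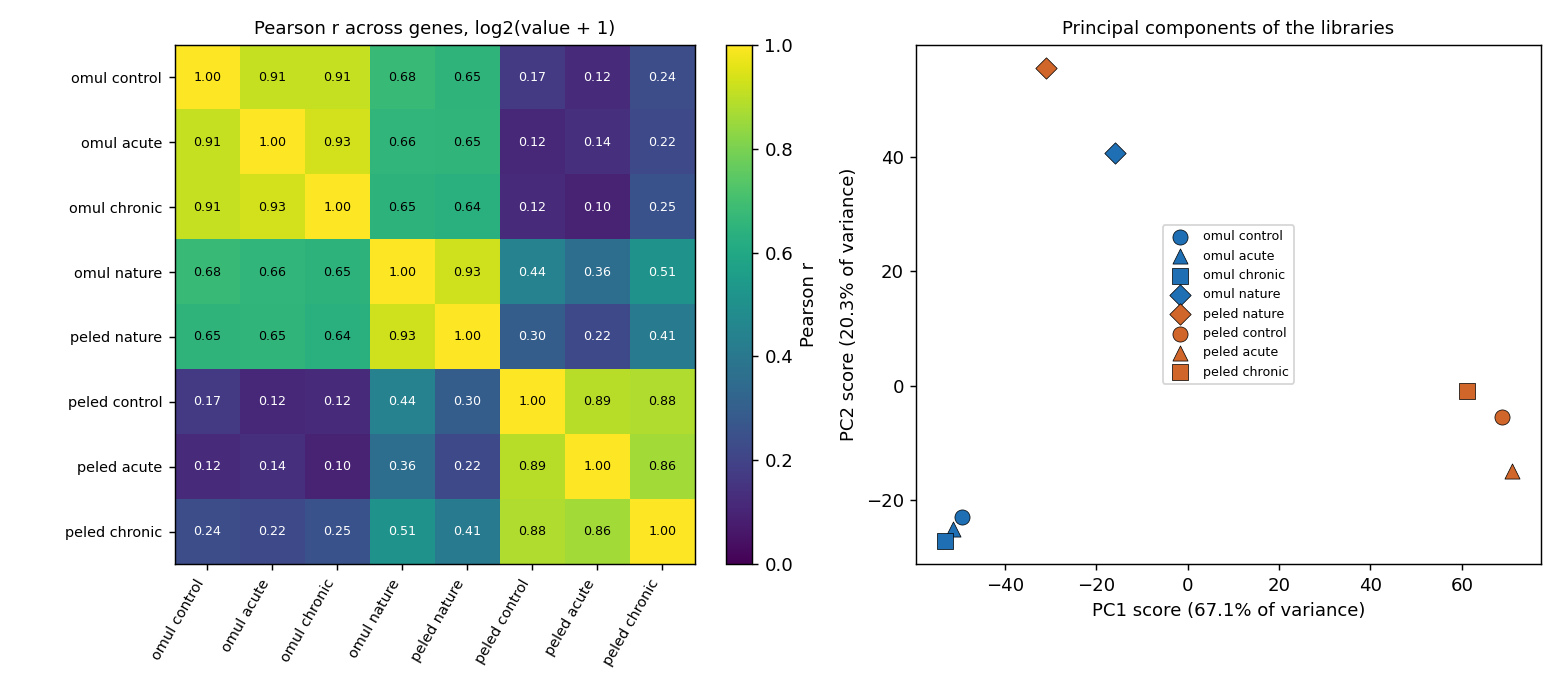
Left, Pearson correlation across 2184 genes of log2(value + 1) for each pair of the 8 libraries (color, 0 to 1). Right, scores of the same libraries on the first principal components, which hold 67.1% and 20.3% of the variance; color gives the species, marker shape the state, and each point is 1 pooled library.

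Acute warming was compared with the aquaculture control to find the response to rapid heating. After 1 h at 21 °C, 15 genes from 12 assembly components rose in both species and 0 fell (limma, adjusted p below 0.05, 2184 genes tested). Their median value went from 2.73 in the omul control to 35.4 in acute omul, and from 1.27 in the peled control to 192 in acute peled. TRINITY_DN15783_c0_g1 went from 3.17 to 138 in omul and from 2.94 to 530.2 in peled, a mean log2 difference of 6.07 (SE 1.17, limma adjusted p = 0.000542). TRINITY_DN46048_c0_g2 went from 1.92 to 80.5 in omul and from 3.51 to 399 in peled, a log2 difference of 5.64 (SE 1.13, limma adjusted p = 0.000726). Over the 15 genes the log2 difference was 3.89 to 6.07, with a median of 4.84. On the lower side values alone are given. TRINITY_DN24812_c0_g1 was at 19.99 in the control and 1.53 in the acute library of omul, and at 32.6 and 5.78 in peled (limma adjusted p = 1). TRINITY_DN75747_c0_g2 was at 4.08 in the omul control and listed at 0 in acute omul, and went from 198 to 25.6 in peled (limma adjusted p = 1).

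A wider set of acute genes was taken from single libraries, without a test. Of the genes at a value of at least 10 in either library, 222 in omul (18.7%) and 235 in peled (19.3%) lay at least 2-fold from the control. In omul 97 were higher and 125 lower, and in peled 149 were higher and 86 lower. Among the 518 genes that reached this level in both species, 36 were higher in both, where independent lists would share 6.53, and 15 were lower in both, where independent lists would share 4.52. The 15 called genes all belong to the 36. In the 36 genes the median log2 ratio was 2.49 in omul and 3.13 in peled, and 31 had the larger ratio in peled. The 97 genes chosen as higher in acute omul were read in the peled libraries, which had no part in the choice, and 66 of them were higher in acute peled, with a median log2 ratio of 0.48 against 0.11 for the upper bound of 95% of random lists. Of the 149 genes chosen in peled 111 were higher in acute omul, with a median of 0.63 and a random upper bound of 0.05. The 86 genes chosen as lower in acute peled had a median of -0.46 in omul (random lower bound -0.23). The 125 chosen as lower in omul had a median of -0.14 in peled, inside the random range of -0.19 to 0.07.

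The number of acute calls depended on single libraries. Without an acute or a control library of 1 species the contrast is no longer a mean over both species. Fewer genes were called in each such fit, but these counts cannot be set beside the 15. The log2 difference was then 5.30 to 6.83 for TRINITY_DN15783_c0_g1 and 4.61 to 6.66 for TRINITY_DN46048_c0_g2. Without chronic omul or without chronic peled there were 3 calls, with the log2 differences of both genes unchanged at 6.07 and 5.64. A pseudocount of 0.1 also left 3. With the 6 aquaculture-reared libraries alone there were 16 calls, 15 higher and 1 lower, of which 12 were among the 15. The lower gene was TRINITY_DN24812_c0_g1, with a log2 difference of -2.68 (SE 0.38, limma adjusted p = 0.0233).

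**Figure D2:**
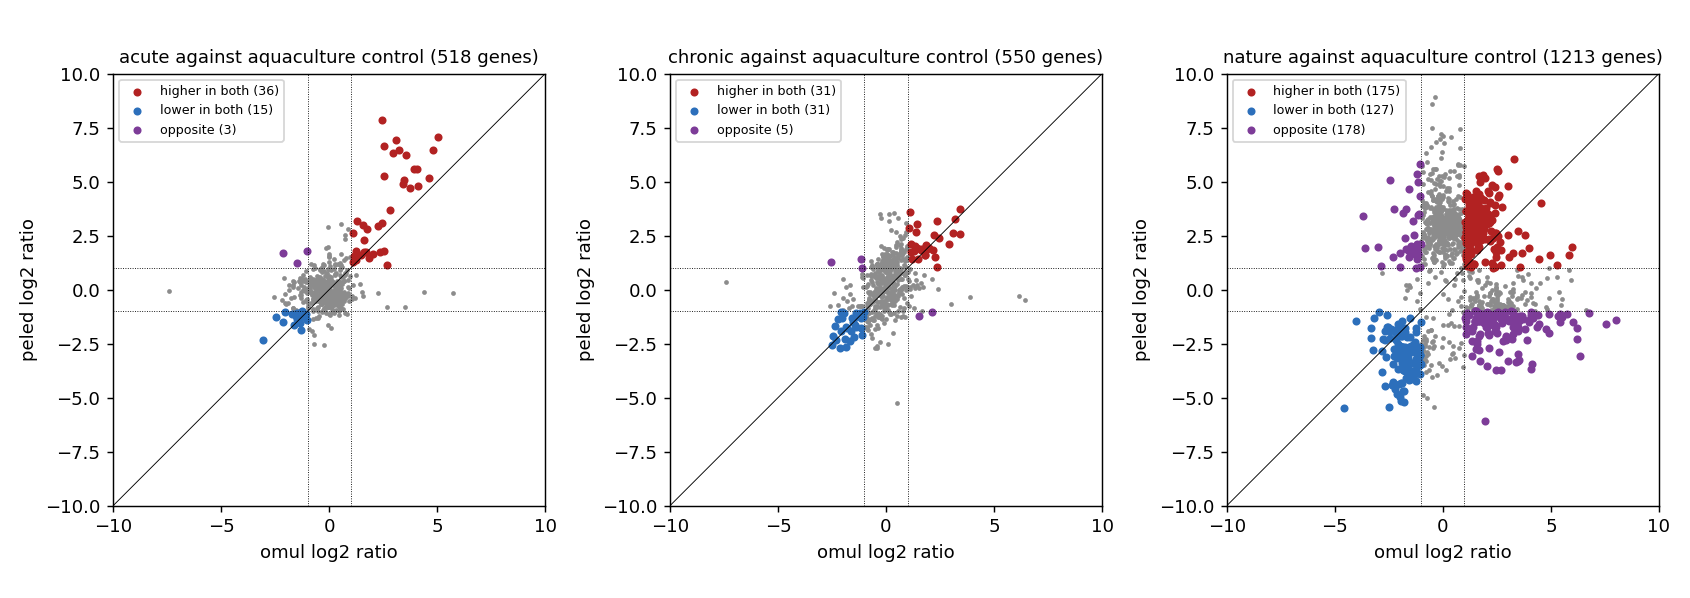
Log2 ratio of each gene in omul (x axis) and in peled (y axis) for acute, chronic and nature against the aquaculture control, at genes with a value of at least 10 in either library of both species. Red, blue and purple points are at least 2-fold higher in both, lower in both, or opposite; 36 genes were higher in both after acute stress and 31 after chronic stress, and 178 were opposite between nature and aquaculture.

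Chronic warming was compared with the same control to find the response to repeated heating. Here 0 of 2184 genes passed limma's test over the 8 libraries, with 22 at an unadjusted p below 0.05. With the 6 aquaculture-reared libraries alone 3 genes rose and 0 fell, with log2 differences of 2.68 to 3.56, and 337 genes had an unadjusted p below 0.05. Leaving out nature omul alone gave 1 call and nature peled alone 3. The median residual SD was 0.97 (log2) with the nature libraries in the fit and 0.38 without them. TRINITY_DN95004_c1_g1 went from 0.59 to 15.9 in omul and from 0.058 to 12.9 in peled, a log2 difference of 3.56 (SE 0.41, limma adjusted p = 0.0352 over 6 libraries, 1 over 8). TRINITY_DN9585_c0_g1 went from 2.20 to 28.4 in omul and from 4.67 to 53.4 in peled, a log2 difference of 3.23 (SE 0.35, limma adjusted p = 0.0352 over 6 libraries, 1 over 8). As values alone, TRINITY_DN16095_c1_g1 was at 38.6 in the control and 6.06 in the chronic library of omul, and at 64.6 and 10.05 in peled. TRINITY_DN34008_c0_g1 was at 32.9 and 5.78 in omul and at 302 and 60.03 in peled. Neither passed with 6 libraries (limma adjusted p = 0.116 and 0.121).

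In single libraries 259 genes of omul (21.6%) and 450 of peled (36.4%) were at least 2-fold from the control after chronic warming. Omul had 131 higher and 128 lower genes, and peled 248 higher and 202 lower. Among 550 genes that could be read in both species, 31 were higher in both (19.0 for independent lists) and 31 lower in both (9.06). The 131 genes chosen as higher in chronic omul had a median log2 ratio of 0.47 in chronic peled (random upper bound 0.22), and the 128 chosen as lower had -0.73 (random lower bound -0.16). Chosen in peled and read in omul, the 248 higher genes had a median of 0.32 (random upper bound 0.08) and the 202 lower genes -0.57 (random lower bound -0.17).

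Chronic was then set against acute warming, a comparison whose log2 difference does not use the control libraries, although its error does. Over the 8 libraries 5 genes were lower after chronic than after acute warming in limma's test and 0 were higher, and all 5 belong to the 36 acute genes. TRINITY_DN51870_c0_g1 was at 70.7 in acute and 2.06 in chronic omul, and at 481 and 16.9 in peled, a log2 difference of -4.65 (SE 1.14, limma adjusted p = 0.0244; 0.0637 over 6 libraries). TRINITY_DN3509_c4_g3 was at 43.7 and 1.04 in omul and at 245 and 8.42 in peled, a log2 difference of -4.58 (SE 1.09, limma adjusted p = 0.0244; 0.0452 over 6 libraries). With 6 libraries 16 genes were lower and 3 higher, 2 of the 5 among them. The higher ones included TRINITY_DN9585_c0_g1, with a log2 difference of 2.93 (SE 0.35), and TRINITY_DN511_c0_g1, with 2.47 (SE 0.34), both at a limma adjusted p of 0.0385 over 6 libraries and 1 over 8. There were 0 calls when either control library was left out, 21 without nature omul and 20 without nature peled. Without an acute or a chronic library the contrast is no longer a mean over both species. Fewer genes were called there too, but these counts cannot be set beside the 5. The log2 difference was then -5.71 to -3.59 for TRINITY_DN51870_c0_g1 and -5.50 to -3.66 for TRINITY_DN3509_c4_g3. There were also 0 calls with a pseudocount of 0.1 or with sums over assembly components, and 9 with a pseudocount of 5.

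The acute genes stood lower after chronic than after acute warming. The 36 genes had a median value of 4.79 in the control, 34.8 in the acute and 8.77 in the chronic library of omul, and of 5.50, 91.2 and 10.9 in peled. In nature they stood at 5.52 in omul and 5.77 in peled. Chronic values lay below acute values in both species for 35 of the 36, and 6 were also at least 2-fold above the control after chronic warming in both. These genes were chosen for high acute values, which by itself lowers the chronic values beside them, so the choice was also made in a single species and read in the other. The 97 genes chosen in omul had a median log2 ratio of chronic to acute of -0.61 in peled (random lower bound -0.24), and the 149 chosen in peled had -0.66 in omul (random lower bound -0.10). The 15 genes lower after acute warming had medians of 24.98, 7.64 and 8.10 in control, acute and chronic omul and of 21.0, 8.23 and 8.68 in peled, and 9 of them were also in the set lower after chronic warming. Both sets use the same control libraries, so high control values alone can place a gene in both. The 125 genes lower in acute omul had a median log2 ratio of chronic to control of -0.133 in peled, inside the random range (lower bound -0.134). The 86 lower in acute peled had -0.63 in omul (random lower bound -0.24).

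**Figure D3:**
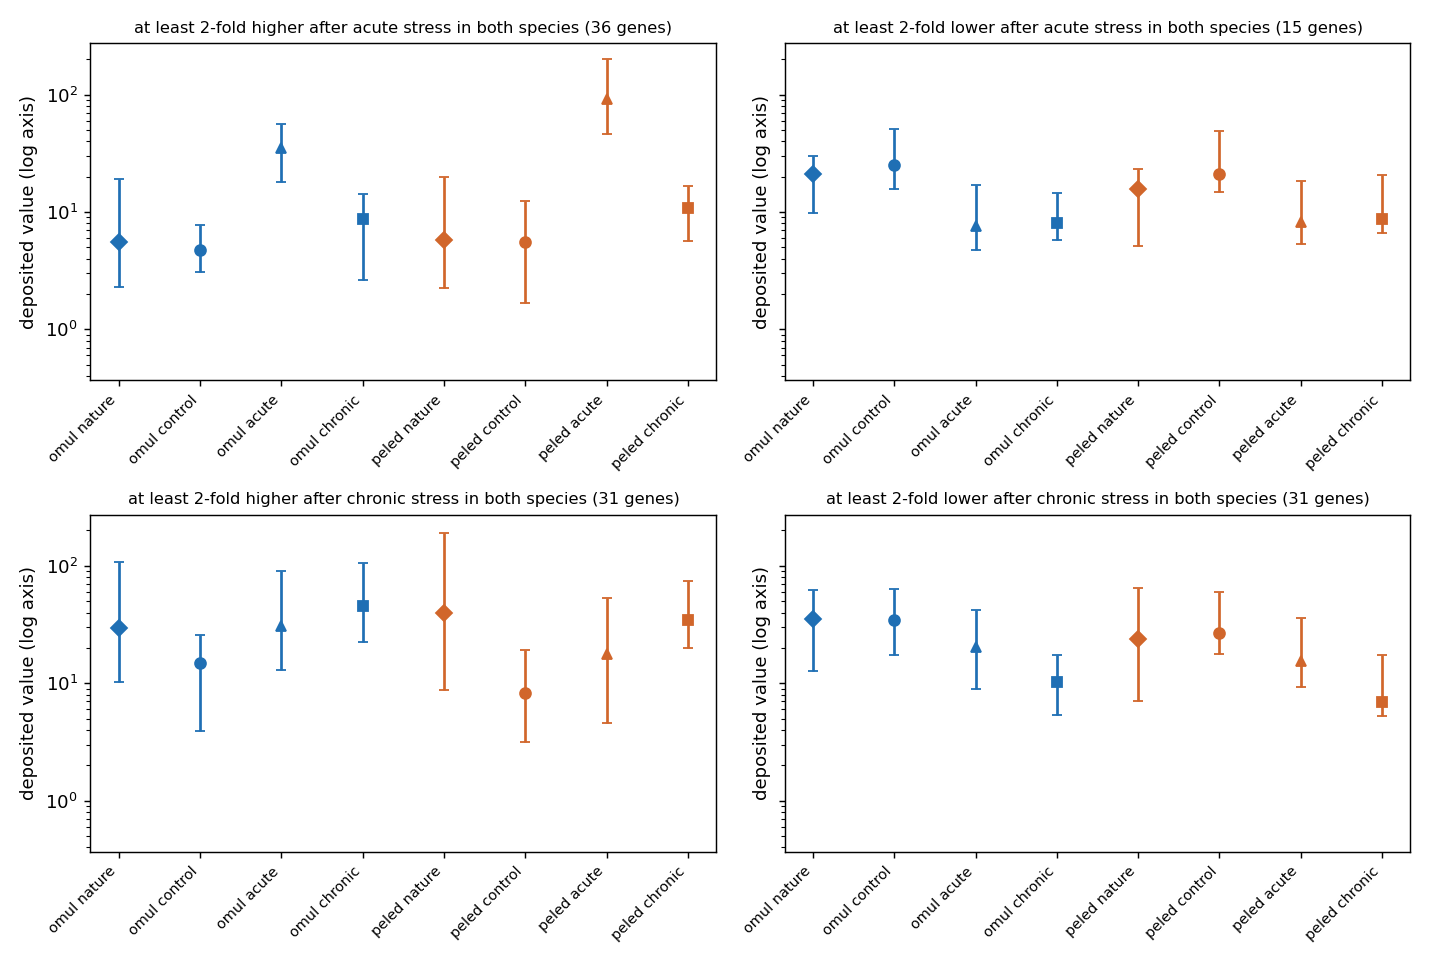
Median deposited value (points, log axis) and interquartile range (bars) over genes in each of the 8 libraries, for the genes at least 2-fold higher or lower in both species after acute (36 and 15 genes) or chronic stress (31 and 31 genes). The sets were chosen on the libraries they separate; the 36 acute genes have medians of 34.8 and 91.2 in the acute libraries and 8.77 and 10.9 in the chronic ones.

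Acute and chronic ratios of a species share its control library, which makes them alike by chance. In omul 40 genes were higher after both (4.97 for independent lists, 30.0 in simulations without any effect) and 66 lower (14.3 and 39.2). In peled 38 were higher (15.3 and 32.1) and 56 lower (15.3 and 39.5). The covariance of the ratios across genes was 0.64 in omul against 0.36 simulated, and 0.37 in peled against 0.35 simulated, with r = 0.76 against 0.56 and 0.38 against 0.55. Each species has a single control library, so the controls cannot be split, and part of the overlap may come from them. The simulated overlaps may be too high, since their noise also holds responses that differ between the species. Between species, where no library is shared, the ratios correlated across genes at r = 0.36 (Spearman 0.17) for acute and 0.33 (Spearman 0.37) for chronic warming, and at 0.013 (Spearman 0.055) for nature against aquaculture.

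Larvae from nature were compared with the unheated aquaculture control to describe how the origins differed. Rearing time and temperature are given for the aquaculture larvae alone. Differences in age or temperature therefore cannot be told apart from origin. In the mean over both species there were 3 calls, 1 higher and 2 lower in nature, while 316 genes had an unadjusted p below 0.05. TRINITY_DN1009_c1_g2 was at 0.10 in nature and 7.31 in aquaculture omul and at 0.34 and 545 in peled, a log2 difference of -5.79 (SE 1.16, limma adjusted p = 0.00139). TRINITY_DN11958_c0_g1 was at 0.34 and 30.9 in omul and at 0.40 and 61.2 in peled, a log2 difference of -5.03 (SE 1.17, limma adjusted p = 0.0182). TRINITY_DN46766_c0_g4 was at 237 in nature peled and listed at 0 in the 3 aquaculture-reared peled libraries, but at 3.52 and 1.29 in nature and aquaculture omul (limma adjusted p = 0.0424). As a value alone, TRINITY_DN299239_c1_g1 was at 104 and 3.46 in omul and at 234 and 13.8 in peled (limma adjusted p = 0.164). TRINITY_DN46766_c0_g4, the only gene called higher in nature, was not called with a pseudocount of 0.1 or with libraries scaled to a common median, and TRINITY_DN11958_c0_g1 was not called with a pseudocount of 5, where 3 genes were higher and 1 lower. Without nature peled the log2 difference of TRINITY_DN46766_c0_g4 was 1.38 and neither it nor TRINITY_DN1009_c1_g2 was called. Without nature omul the log2 difference of TRINITY_DN46766_c0_g4 was 7.50. With 1 nature library left out, the contrast is no longer a mean over both species but rests on the nature library of the other. Its error then comes from the aquaculture-reared libraries alone, so counts of calls from such fits cannot be set beside the 3. The calls also depended on single aquaculture-reared libraries, and were fewer whichever of these was left out.

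Within each species more genes differed between nature and aquaculture than after warming. At least 2-fold apart were 792 genes in omul (54.8%), with 477 higher and 315 lower in nature, and 1464 in peled (87.9%), with 803 higher and 661 lower. Of 1213 genes read in both species 175 were higher in both, fewer than the 268 of independent lists, 127 were lower in both against 48.0, and 178 were opposite. The number of opposite genes in independent lists was not computed. The median of all genes lay 0.57 (log2) higher in nature in the 8-library fit, and 0.39 higher after scaling to a common median. That scaling, chosen after the data were seen, turned the balance in omul to 382 higher and 399 lower (48.9% higher against 60.2%), while peled kept more higher than lower genes (757 and 702).

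Peled was compared with omul over the 4 states, the species differences that state leaves in place. In limma's test 392 genes were higher in peled and 391 lower, 783 in all, and the sign was the same in each of the 4 states for 76 of the higher and 172 of the lower genes. TRINITY_DN92432_c0_g1 was 5.92 (log2) higher in peled (SE 0.88, limma adjusted p = 8.12e-09), and TRINITY_DN75747_c0_g1 5.24 higher (SE 0.93, limma adjusted p = 1.85e-06). TRINITY_DN6945_c3_g2 had a difference of -5.54 (SE 0.84, limma adjusted p = 1.74e-08) and TRINITY_DN29953_c0_g2 of -5.36 (SE 0.88, limma adjusted p = 1.91e-07). The sizes were uneven over the states. TRINITY_DN92432_c0_g1 was at 338 in the peled and 1.70 in the omul control, but at 153 and 142 in nature. TRINITY_DN29953_c0_g2 was at 0.49 in the peled and 255 in the omul control, but at 188 and 233 in nature. TRINITY_DN75747_c0_g1 was at 343 in the omul control and at 1.02 and 1.05 in the heated omul libraries, and its call was lost without either chronic library (limma adjusted p = 0.143 and 0.119).

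More genes differed between the species in the aquaculture-reared libraries than in those from nature. In the 6 aquaculture-reared libraries alone, a comparison added after the data were seen, 1844 genes differed, 845 higher in peled and 999 lower. The median absolute log2 difference was 2.10 there and 0.57 in nature, and at least 2-fold differences numbered 1818 and 523. By single libraries at least 2-fold differences reached 86.4% of genes in the controls, 89.4% after acute and 81.8% after chronic warming, and 24.9% in nature. In nature 163 genes were higher in peled and 159 lower, or 201 and 126 after scaling to a common median and 172 and 265 at a value of at least 5 in the higher library. A fit of the change in the species difference between origins called 1307 genes, and in 1232 of them the absolute difference was smaller in nature than in aquaculture. Its error came from the aquaculture-reared libraries of 3 states alone, with 1 nature library per species, so it holds no measure of the spread between nature pools. With 1 nature library left out, the other has a state term to itself and adds nothing to the species difference. The fit then compares aquaculture-reared libraries alone. TRINITY_DN92432_c0_g1, for instance, was 7.86 (log2) higher in peled without either of them, as in the 6-library fit. Such a fit says nothing about the count of 783 over the states. Leaving out an aquaculture-reared library lowered it, to 41, 55 and 20 without control, acute and chronic omul and to 43, 57 and 21 without those of peled.

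**Figure D4:**
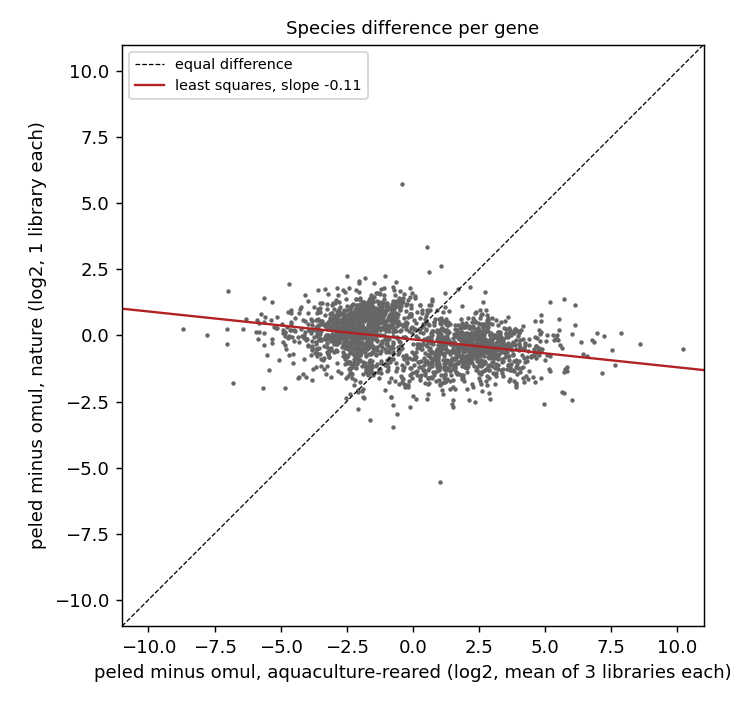
Each point is a gene, with the peled minus omul log2 difference in aquaculture-reared larvae (x axis, mean of 3 libraries each) and in larvae from nature (y axis, 1 library each). The dashed line marks equal differences and the red line is the least squares fit, whose slope is -0.11.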

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

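The tests on mixed or exchanged larvae and on the size of the acute ratios were chosen only after those patterns had been seen, while the splits of the samples and the comparison of genes from shared assembly components were set beforehand.

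The species difference was not alike in the libraries of each origin. A fit of its change between nature and aquaculture-reared larvae called 1307 genes, with the smaller species difference in nature at 1232 and the larger at 75. The aquaculture-reared libraries of different states stand in for replicates there and each nature group is 1 library, so the count does not weigh the spread between nature pools. Opposite responses in the species were also flagged, with 178 genes at least 2-fold higher in nature larvae of 1 species and lower in those of the other (139 of them higher in nature omul). After acute warming 3 genes, and after chronic warming 5 genes, went in opposite directions by that measure. These 3 counts of opposite genes were not tested, since each rests on single libraries. The number that independent lists would hold was not computed, so none of the 3 is shown to be an excess.

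The nature libraries of the species were alike while the aquaculture-reared ones were far apart, and the species labels of the nature libraries may be doubted on that ground. Exchanged labels would not make the libraries alike, but they stay open. The slope of the nature on the aquaculture species difference was -0.11 (95% interval -0.12 to -0.09, over genes), which goes with an exchange. Exchanging the nature libraries raised the species calls from 783 to 1333, but this draws on the same values and adds no separate support. Small sets of 11 omul-only and 37 peled-only genes were named from aquaculture-reared larvae, where their median in the other species was 0. In nature all 11 were listed above 0 in peled and all 37 in omul. The omul-only genes ran against an exchange, at 0.21 of the omul level in nature omul and 0.113 in nature peled, with overlapping intervals. The peled-only genes, at 0.19 (0.14 to 0.21) and 0.096 (0.072 to 0.12) of the peled level, go with an exchange, but both sets were lower in nature peled. That 0.113 leaves omul larvae in the library labelled nature peled open too, since nature omul itself was low. A mixture of RNA of both species is not decided either. The shares summed to at most 0.398 at genes of 1 species only and to 1.12 and 1.10 at wider sets. A mixture and an unmixed library would both sum to about 1, so these sums cannot tell them apart. Separate assembly of the same gene from each species would by itself keep the species apart in nature too. The median absolute log2 difference was 0.57 there and 2.10 in aquaculture-reared larvae. As a part of the species difference, separate assembly stays open. Of 113 gene pairs of a component, 79 had both genes at least 2-fold apart. Of these, 39.2% differed in opposite directions against 49.5% in permuted pairs (one-sided permutation p = 0.036). That share lay inside the permuted 95% range of 38.5 to 60.5. The lower tail set beforehand as the criterion was too weak. Components with 2 or more genes hold only 205 of 2184 genes, and copies in separate components are missed. Whether origin acted differently in the species stays open, because each combination has 1 library.

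For the species contrast over the 4 states, chance is not excluded. Of 32 fitted splits of the 8 libraries into 4 and 4 (35 exist, and 3 could not be fitted), 2 called at least 783 genes, the real split with 783 and 1 other with 1333. That other split exchanges the nature libraries, so it bears on the doubt about their labels as well as on the likeness of the nature libraries. Many of the splits put both libraries of a state in the same group, which the real contrast does not. The splits that keep each state paired are too few for a share under 0.05. Within the 6 aquaculture-reared libraries the real split called 1844 genes and the highest other 1; with 1 of 10 splits as large, the splits are too few for a share under 0.05.

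At the 36 genes at least 2-fold higher after acute warming in both species, of which 15 passed the test, the log2 ratio was larger in peled by a median of 0.90 (95% interval over genes, not pools, 0.54 to 1.51), whereas of the 15 genes lower in both only 4 had the larger change in peled. A scaling offset would show the same excess at other genes, but 1161 genes chosen by their nature and chronic libraries, which are not in these ratios, had a median excess of 0.01 (-0.05 to 0.08). Lower control values in peled as the whole cause would set its control below that of omul by about the excess, but the peled minus omul control difference at the 36 genes was 0.29 (-0.32 to 0.88), a bound set after this value had been seen. At the 15 genes that passed the test the median control value was lower in peled, at 1.275 against 2.73 in omul. Lower control values as a part of the excess therefore stay open for those 15. A larger ratio in peled larvae is a hypothesis for these genes that the values may allow, in 1 pool per species, and a difference in the warming or timing of the pools was not tested.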

How the results depend on the processing

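The common median, the prior without a trend, the component sums, the value limits of 5 and 20, and the mean of at least 10 for agreement were chosen after seeing the data. With each library left out in turn the calls ranged from 0 to 16 for acute against control, 0 to 3 for chronic against control, 0 to 21 for chronic against acute, 0 to 1569 for nature and 20 to 1845 for species. For species within the aquaculture-reared libraries they ranged from 1580 to 1864, and for the change of the species difference from 1088 to 1473, where only aquaculture-reared libraries could be left out, as each nature group is 1 library. A state then left with 1 library is assumed to vary like the others. Not all of these fits make the same comparison. Without a library of a state, contrasts that use that state are no longer means over both species. Without a nature library, the species contrast compares aquaculture-reared libraries alone. The upper ends of the ranges for nature and for species over the states come from fits without a nature library. These 2 ranges therefore do not show how stable a single contrast is. A pseudocount of 0.1 left 3 acute calls and 0 for chronic against acute, and a pseudocount of 5 gave 9 for the latter. The prior without a trend gave 3 for chronic against acute and 6 for nature, and component sums gave 0 for chronic against acute. The 6 aquaculture-reared libraries gave 3 chronic calls and 19 for chronic against acute, in a fit without the spread that the nature libraries add.

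At 1.5-fold the genes apart numbered, for omul and peled, 451 and 439 after acute and 509 and 738 after chronic warming, 382 for omul chronic against acute, and 649 between species in nature. With a value of at least 20 they were 119 and 152 after acute warming, 129 for chronic omul, 448 and 917 for nature, 101 for omul chronic against acute, and 213, 829, 874 and 712 between species in nature, control, acute and chronic larvae. These follow from the limits themselves. A pseudocount of 5 left 144 acute and 167 chronic genes in omul. Agreement between species moved to 0.17 for acute, 0.37 for chronic and 0.055 for nature as Spearman's rho. It moved to 0.27, 0.26 and -0.039 with a pseudocount of 0.1, to 0.074 for nature with a pseudocount of 5, and to 0.43 for acute at a mean of at least 10. The cause of these moves, and of those with other pseudocounts, priors and component sums, was not tested. No alternative run here turned the sign of a named gene that had been called. Over the named genes and the alternatives, 47 results lost and 17 gained a call and 192 stayed on their side of the threshold. Counts that stayed within 1.5 times their value and correlations that stayed within their spread over genes numbered 111, and 65 went beyond that limit of their own kind.

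The count-based alternatives (TMM and median-of-ratios factors, DESeq2, count filters, library sizes without the 10 most abundant genes) and the gene list tests were not run, as there are no counts or gene names. The absence of a filter on low values changes nothing, since the filter removed 0 genes. Depth is unknown and limits all low values.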

Other observations

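The test of chronic genes in nature larvae was set before its result was seen. The shares of each species' level were read after the clusters of libraries had been seen.

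Both nature libraries lay above or below all 6 aquaculture-reared libraries at 682 genes (31.2%), where chance gives 7.14%. With a margin of 2-fold there were 154 (7.05%), 66 above and 88 below, and chance with that margin was not computed. Among the aquaculture-reared libraries all 3 of peled lay above or below all 3 of omul at 1756 genes (80.4%), where chance gives 10%, and with a margin of 2-fold 585 genes were higher in peled and 619 in omul. Both chance shares assume exchangeable libraries. The libraries fall into clusters and the list holds no gene of steady level, so an excess over these shares is no test. At the 619 omul-higher genes, nature omul stood at a median of 0.74 and nature peled at 0.88 of the way from the peled to the omul level. At the 585 peled-higher genes they stood at 0.38 and 0.22 of the way from the omul to the peled level, so that nature peled lay nearer to aquaculture-reared omul than to its own species at both sets.

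Genes of chronic warming were also read in nature. The 31 genes higher after chronic warming in both species had medians of 14.9 in control, 30.8 in acute, 45.7 in chronic and 29.5 in nature omul, and of 8.32, 17.6, 34.4 and 40.0 in peled. These genes and the control libraries were used in the choice, so the medians are not independent of it. A hypothesis that chronically warmed and nature larvae share higher genes was tested by choosing genes in 1 species and reading the nature ratio in the other. The 131 genes chosen in omul had a median log2 ratio of nature to control of 1.296 in peled, at the percentile of 95 among random lists, and the 248 chosen in peled had 0.62 in omul, at 100. Genes lower after chronic warming stood at 63.8 in peled, inside the random range, and at 99.97 in omul, so in omul the reading may not be tied to the direction of the chronic response. Genes higher after acute warming stood at 73.5 in peled and 50.83 in omul, and the difference from the chronic genes was not tested. The hypothesis stays undecided.

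The chronic and acute libraries were further apart in peled than in omul. Between the chronic and the acute library 481 genes of peled (38.8%) and 164 of omul (14.2%) were at least 2-fold apart, each from 1 pool per state and with no test of the difference.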
